A study of Arabidopsis thaliana with 24 samples.

How the data were processed

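RNA was measured in whole seedlings of 4 Arabidopsis genotypes (WT Col-0, pif7, asf1ab, hira) at 6 days of age, kept in white light or given 1 hr of shade, with 3 libraries for each of the 8 combinations. Per the submitters' processing notes, reads were handled with FastQC, cutadapt, STAR, HTSeq and DESeq2 against the TAIR10 genome; versions are not given in the sources used here. The values used are the deposited FPKM of the authors, a single table of 33020 loci by 24 libraries written to 2 decimals. How FPKM was derived, and how the 187 assembled loci with MSTRG names were made, is not given in the sources used here. The values match FPKM in scale: summed values differ between libraries, and low values step in units that fall with gene length. From those steps in genes of up to 900 exonic bases with at most 6 reads, the depth was read as 13400000 to 18200000 reads per library, with intervals from 100 bootstrap resamples. Raw reads were not used here. The labels do not say whether the 3 libraries of a group come from separate cultures, so every p-value measures only the spread between these samples.

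Of the loci, 6045 are 0 in every library, 133 are plastid and 152 mitochondrial, and 32548 carry a locus identifier found in the TAIR10.1 annotation. That annotation was used only for gene names, gene order and the exon lengths of the depth estimate, because the authors' build is TAIR10. All 377 listed loci are in the table; 365 of their symbols match that annotation and 12 do not. Values were transformed to log2(FPKM + 1), and the 19126 genes with a mean FPKM of at least 1 over the 24 libraries were tested. An exact 0 can stand for a failed estimate, so genes at 0 in all libraries of a group are given by their library values without a fold change. In each library the shares of ribosomal RNA (4 loci), plastid and mitochondrial transcripts were summed.

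All tests used limma 3.58.1 in R 4.3.3: a model with 8 group means, moderated variances with an intensity trend (eBayes with trend = TRUE), and Benjamini-Hochberg adjustment over the genes tested within a contrast, with calls at an adjusted p below 0.05. Contrasts were shade minus white light in each genotype, the difference of each mutant's shade response from that of WT, and each mutant against WT in white light. Contrasts of mutants against WT in shade were used only to find genes changed in both lights. The DNA damage list in shaded hira is not reported here. Errors are the standard errors of the contrast, or the SD of 3 libraries for FPKM values. Fixed gene lists of at least 4 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, and again with a correlation estimated from the data. The 25 lists are core shade-induced genes; auxin biosynthesis and transport; Aux/IAA and GH3; SAUR; brassinosteroid; gibberellin; ethylene; cell wall loosening; light receptors and signalling; photosynthesis and chlorophyll; circadian clock; histone chaperones and H3 genes; DNA damage; DNA replication; mitosis; salicylic acid and immunity; jasmonate; heat shock, touch and handling; root, shoot meristem, stomatal and seed maturation markers; senescence and dark starvation; plastid-encoded; and mitochondrion-encoded genes. The share of the WT response kept in a mutant was computed on genes chosen in a fit without the WT replicate used to measure it, for each of the 3 replicates in turn. Shared differences between mutants were compared with 20 simulations of unchanged groups that share the WT libraries. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

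Contrasts, gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The rule names PIF7, ASF1A, ASF1B and HIRA. For shade in WT it names the 14 largest rises and 8 largest falls among called genes whose 3 libraries in the higher light all lie above the other 3 and whose mean there is at least 2 FPKM, and for each mutant 5 rises and 3 falls. It adds the 6 largest differences each way in shade response, the 8 largest each way in white light, all core members and up to 4 called members of every other list, or the 2 largest where none was called. Alternatives were: only the libraries of the groups compared, rescaling by the median of ratios, quantile normalization, each library left out in turn, a change of at least 1 log2 unit, a mean FPKM of at least 5, no filter, the replicate number as a block, pseudocounts of 0.1 and 5, no variance trend, fry in place of camera, and an estimated correlation. Label exchanges used all 10 splits of a pair of groups and, for the differences in shade response, 100 splits drawn with a fixed seed from the 200 of a pair of groups in both lights. The contrasts were also tested on simulated data with 200 changed genes of 19126, 50 at each size: for shade in WT 34, 88, 98 and 96% were recovered at 0.5, 1, 2 and 3 log2 units with 4 unchanged genes called, for the hira difference in shade response 14, 82, 96 and 98% with 5, and for hira in white light 38, 88, 90 and 98% with 2.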

Results

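Gene expression was measured by RNA sequencing in whole Arabidopsis seedlings at 6 days of age, in wild type (WT, Col-0) and in the mutants pif7, asf1ab and hira. Each genotype was kept in white light or given shade with a red to far-red ratio of 0.4 for 1 hr, with 3 libraries in each of the 8 groups and 24 libraries in all. The authors' FPKM values sum to 778266 to 893997 per library, and 18427 to 19298 genes reach an FPKM of 1 in a library. Depth, read from the spacing of low FPKM values, lies between 13400000 and 18200000 reads. Ribosomal RNA takes 0.72 to 8.32% of the summed FPKM, with 6.27 ± 2.69% in white-light hira against 2.11 ± 0.606% in white-light WT and 2.46 ± 0.320% in shaded hira (mean ± SD, n = 3). Plastid-encoded transcripts were also highest in white-light hira, at 2.30 ± 0.803% against 0.873 ± 0.032% in white-light WT. Replicates 1 and 2 of white-light hira are highest in both, at 8.32 and 7.27% ribosomal RNA and 2.5 and 2.99% plastid transcripts. Replicate 3 reads 3.22 and 1.42%. Changes are log2 ratios of FPKM + 1 with their standard error, from a limma fit of 19126 genes. The added 1 makes the change of a weakly expressed gene too small. The whole distribution shifts between some groups, by a median log2 of 0.119 for shade in pif7, 0.137 for shade in hira and -0.117 for hira against WT in white light. It also shifts by 0.106 and 0.114 for the differences in shade response of pif7 and hira from WT. Medians after rescaling by the median of ratios are therefore given beside most list medians of those contrasts.

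What do the genes that name the mutants show? PIF7, a phytochrome-interacting bHLH factor, stands at 27.4 ± 2.29 FPKM in white-light WT and at 1.11 ± 0.522 in pif7, a fall of -3.78 ± 0.141 log2 (adjusted p = 2.56e-12). Shade itself lowered PIF7, by -1.09 ± 0.141 in WT, -1.63 ± 0.141 in asf1ab and -1.52 ± 0.141 in hira. ASF1B, a histone H3-H4 chaperone gene, fell from 9.50 ± 1.28 FPKM in WT to 1.87 ± 0.194 in asf1ab, by -1.87 ± 0.118 log2 (adjusted p = 3.67e-09). Its paralogue ASF1A was lower in white-light asf1ab by -0.40 ± 0.098 (adjusted p = 0.00642), yet stood at 14.8 ± 2.36 FPKM in shaded asf1ab and 12.6 ± 0.668 in shaded WT. HIRA, the chaperone of replication-independent H3.3 deposition, read 3.91 ± 0.404 FPKM in white-light hira against 4.88 ± 0.241 in WT (-0.26 ± 0.091, adjusted p = 0.0664). In shade HIRA read 4.81, 4.76 and 4.13 FPKM in the hira libraries and 4.59, 5.2 and 4.72 in those of WT. A gene-level FPKM also counts transcript made outside an insertion, so the ASF1A and HIRA values check their mutations only weakly.

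How did WT respond to shade? ATHB2, a homeodomain-leucine zipper gene and long-used shade marker, rose from 4.03 ± 0.877 to 147.6 ± 3.77 FPKM (4.90 ± 0.145 log2, adjusted p = 8.06e-15). The bHLH genes PIL1 and HFR1, which act in shade signalling, rose by 4.26 ± 0.110 and 3.601 ± 0.130. FLP1, an FPF1-like gene, had the largest rise, 6.24 ± 0.283, from 0.770 to 124.9 FPKM. IAA29, a repressor of auxin signalling, rose by 6.07 ± 0.210 and the related IAA19 and IAA6 by 4.68 ± 0.274 and 4.30 ± 0.151. GH3.3, which conjugates auxin, rose by 4.90 ± 0.307, and YUC8, a flavin monooxygenase of auxin synthesis, by 4.37 ± 0.173. Further large rises came from AT3G21330, a bHLH gene (4.55 ± 0.154), SAUR22 (4.42 ± 0.128), RTFL18, a small-peptide gene (4.37 ± 0.256), and ST2A, a jasmonate sulfotransferase (4.35 ± 0.416). AT5G44260, a CCCH zinc-finger gene, rose by 4.11 ± 0.169 and ACS8, an ethylene synthesis gene, by 4.08 ± 0.167. The steadiest large falls were XTH31, a xyloglucan-modifying enzyme gene (-3.06 ± 0.229, adjusted p = 5.46e-09), APR3, an APS reductase gene (-2.97 ± 0.303), and AT4G34550 (-2.68 ± 0.283). The plastid genes ATCG00070 (-3.23 ± 0.973), ATCG01020 (-2.97 ± 1.03) and ATCG00700 (-2.96 ± 1.08) and the loci AT4G08555 (-3.12 ± 0.993) and AT3G04255 (-3.11 ± 1.07) fell with errors near 1. In all, 5043 of 19126 genes changed, 2854 higher and 2189 lower, and 919 of them by at least 1 log2 unit.

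**Figure D1:**
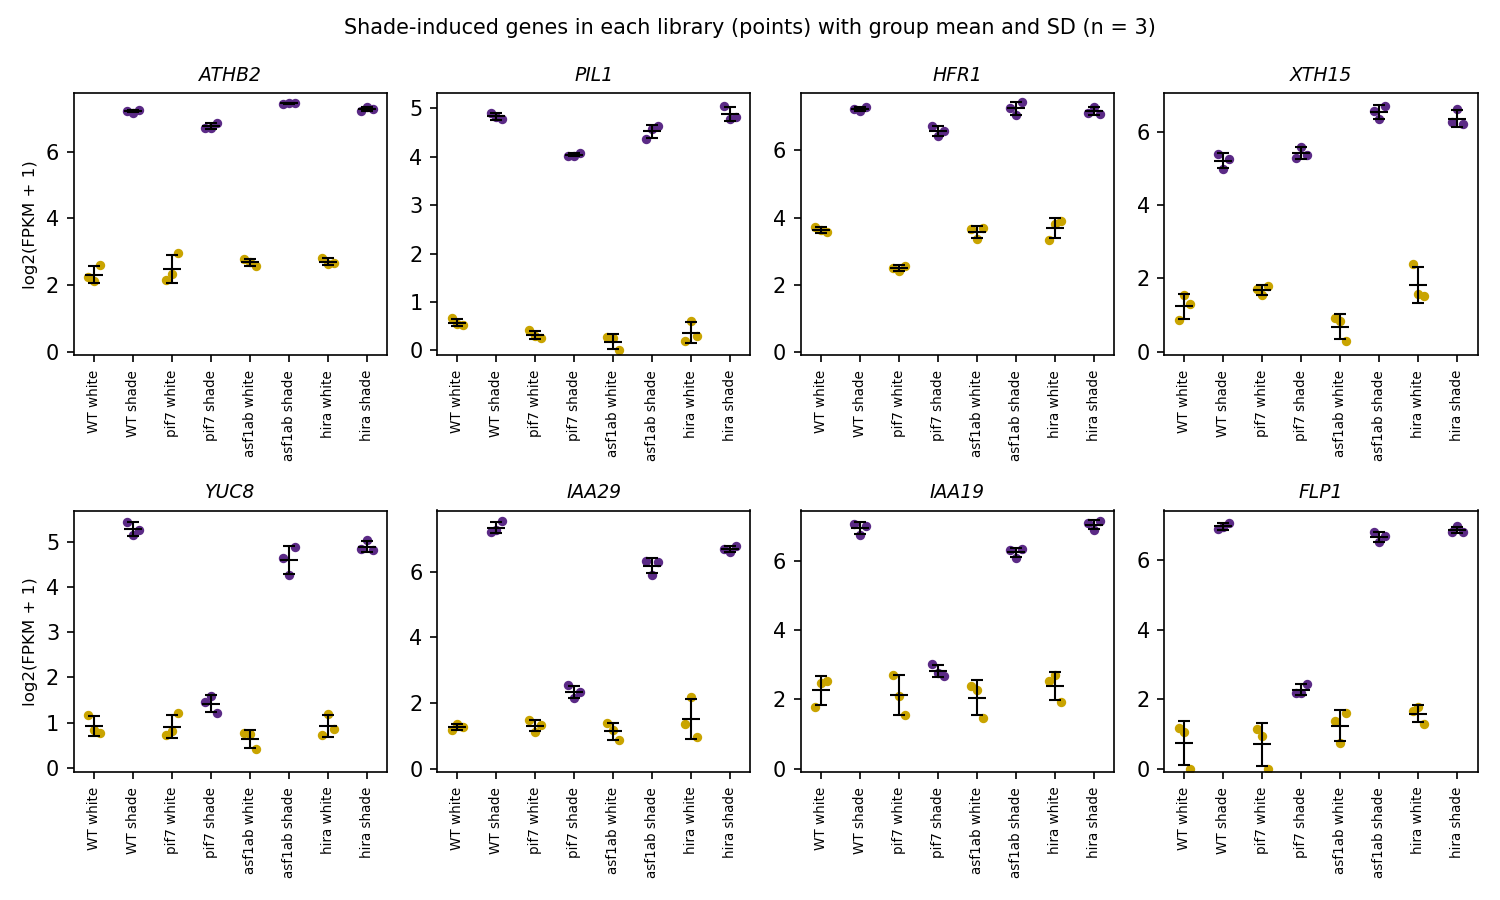
Values of log2(FPKM + 1) for ATHB2, PIL1, HFR1, XTH15, YUC8, IAA29, IAA19 and FLP1 in the 8 groups. Points are single libraries, and bars are the group mean of the log2 values with its SD (n = 3). Before the transformation, the mean of ATHB2 is 4.03 FPKM in white-light WT and 147.6 in shaded WT.

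Growth-related families rose in shaded WT. All 22 core shade-induced genes rose, and 22 also when adjusted over the list alone, with a median log2 of 3.04 (camera, adjusted p = 1.11e-37). In auxin biosynthesis and transport 9 of 12 rose and 3 fell, the same when adjusted over the list alone, among them YUC9 (3.74 ± 0.127), the efflux carrier PIN3 (1.77 ± 0.105) and YUC2 (1.65 ± 0.115); median 1.15, adjusted p = 6.73e-06. Of 30 early auxin genes of the Aux/IAA and GH3 families 24 rose and 1 fell, or 25 and 2 adjusted over the list alone (median 1.16, adjusted p = 4.02e-20). The SAUR genes, short-lived auxin-induced messages, had 24 of 28 risen, 24 adjusted over the list alone, with SAUR1 at 3.87 ± 0.177 and SAUR28 at 3.78 ± 0.231 (median 2.29, adjusted p = 2.05e-28). SAUR19 to SAUR24 are near-identical copies, so reads are not surely assigned among SAUR22, SAUR23 and their neighbours. Brassinosteroid genes had 11 of 15 risen and 1 fallen, unchanged when adjusted over the list alone, including BEE1 (2.82 ± 0.101), the hormone-inactivating BAS1 (2.05 ± 0.133) and the receptor gene BRI1 (1.64 ± 0.107); median 0.63, adjusted p = 4.07e-09. Gibberellin genes gave 4 of 13 risen, 5 adjusted over the list alone, namely the synthesis genes GA20OX2 (2.59 ± 0.176) and GA20OX1 (1.70 ± 0.177) and the DELLA genes GAI (1.72 ± 0.170) and RGL3 (1.51 ± 0.140), with adjusted p = 0.00115. In the ethylene list 6 of 9 rose, 6 adjusted over the list alone, with ACS11 at 2.96 ± 0.147 and ACS4 at 1.85 ± 0.131 (adjusted p = 4.38e-05).

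Other lists moved less evenly in WT. Cell wall loosening genes split into 11 risen and 6 fallen of 23, 12 and 6 adjusted over the list alone, with XTH22 at 3.42 ± 0.241 and XTH33 at 2.96 ± 0.154; camera gave adjusted p = 0.0126, and adjusted p = 0.304 with an estimated correlation. Light receptors and signalling had 7 risen and 10 fallen of 26, 8 and 10 adjusted over the list alone. PHYA rose by 1.65 ± 0.108 and PHYB by 1.24 ± 0.097, while the bZIP genes HYH and HY5 fell by -0.95 ± 0.117 and -0.86 ± 0.122 (list adjusted p = 0.612). Photosynthesis and chlorophyll genes had 3 risen and 5 fallen of 24, also adjusted over the list alone, with RBCS1B, near-identical to other RBCS copies, at -0.86 ± 0.162 and the LHCB1.2 copy at 0.74 ± 0.245 (adjusted p = 0.706). Clock genes had LUX higher by 0.77 ± 0.144 and ELF4, FKF1 and ZTL lower, 1 and 3 of 15, or 1 and 4 adjusted over the list alone (adjusted p = 0.0888). In the list of histone chaperones and H3 genes 2 of 20 rose, MRG1 (0.32 ± 0.073) and HTR8 (0.20 ± 0.066), and 1 adjusted over the list alone (adjusted p = 0.700). None of 14 DNA damage genes was called, nor adjusted over the list alone, with the DNA synthesis gene TSO2 at -1.31 ± 0.807 (list adjusted p = 0.0888). Replication genes had 1 of 12 fallen, MCM7 at -0.39 ± 0.138, and 0 adjusted over the list alone, at adjusted p = 0.0161 and adjusted p = 0.648 with an estimated correlation. Mitosis genes had 0 of 13 called, and 0 adjusted over the list alone, AUR1 reading 0.29 ± 0.142 (adjusted p = 0.700). PAD4 of the salicylic acid and immunity list fell by -0.98 ± 0.191, 1 of 13 in both counts, with 1 adjusted over the list alone (adjusted p = 0.281).

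Stress and marker lists in WT were mostly uncalled. Jasmonate genes had 3 of 17 risen, 3 adjusted over the list alone, with JAZ7 at 1.46 ± 0.378 and AOS at 0.60 ± 0.149 beside ST2A (adjusted p = 0.113). Among heat shock, touch and handling genes 3 of 12 rose, 3 adjusted over the list alone, with the calmodulin-like TCH3 (1.49 ± 0.326) and TCH2 (1.05 ± 0.132), at adjusted p = 0.0888. Root markers gave 2 of 5 fallen, 2 adjusted over the list alone, the phosphate transporter PHT1;1 by -0.98 ± 0.269 and SCR by -0.26 ± 0.079 (adjusted p = 0.431). Shoot meristem markers gave 2 of 6 fallen, CUC3 and AS1, and 2 adjusted over the list alone (adjusted p = 0.181). In the stomatal list the guard-cell potassium channel gene KAT1 rose by 1.89 ± 0.115 and MYB60 fell by -0.32 ± 0.093, 1 each of 6 and 1 each adjusted over the list alone; the median is -0.115 while camera ranks the list upward (adjusted p = 0.869). Seed maturation genes had 3 of 13 risen, 3 adjusted over the list alone, EM6 by 1.52 ± 0.387 (adjusted p = 0.202). Senescence and dark starvation genes had ASN1, an asparagine synthetase gene, up by 3.48 ± 0.304 and SGR1 down by -0.41 ± 0.116, 2 and 1 of 5, or 2 and 2 adjusted over the list alone. Here too the median of -0.301 and the upward camera rank differ in sign (adjusted p = 0.431). Plastid-encoded genes had 4 of 75 fallen and 0 adjusted over the list alone (adjusted p = 0.0888), and mitochondrion-encoded genes 1 of 28 fallen, ATMG00510, and 0 adjusted over the list alone (adjusted p = 0.458).

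Which parts of the shade response change without PIF7? In pif7, IAA29 rose by only 1.03 ± 0.210 and its shade response was smaller than in WT by -5.04 ± 0.298 log2 (adjusted p = 1.23e-09). FLP1 responded less by -4.67 ± 0.400, GH3.3 by -4.33 ± 0.435, AT3G21330 by -4.21 ± 0.218, IAA19 by -3.98 ± 0.388, YUC9 by -3.88 ± 0.179 and YUC8 by -3.85 ± 0.244. Other genes kept most of their response: ATHB2 rose by 4.29 ± 0.145 (difference -0.61 ± 0.205, adjusted p = 0.0781), XTH15, a xyloglucan-modifying enzyme gene, by 3.74 ± 0.215 (difference -0.25 ± 0.305, adjusted p = 0.646), and PIL1 by 3.72 ± 0.110 (difference -0.54 ± 0.155, adjusted p = 0.0430). HFR1 rose by 4.08 ± 0.130 from a lower white-light level, 4.63 ± 0.322 FPKM in pif7 and 11.4 ± 0.685 in WT. ASN1 rose by 4.21 ± 0.304 in pif7, and XTH31 fell by -3.50 ± 0.229. PDF1.3, a defensin gene, fell by -3.95 ± 0.613 in pif7 and differs from WT by -4.58 ± 0.867. The AP2/ERF gene AT5G51190 also had a lower response in pif7 by -4.61 ± 0.652 (adjusted p = 0.000167). Responses were larger in pif7 for U4.10 (3.79 ± 1.101), AT1G07567 (2.51 ± 0.652), the 12S storage protein gene CRA1 (2.43 ± 0.714), AT3G20340 (2.26 ± 0.606), AT2G34317 (2.06 ± 0.399) and TOM7-2 of the mitochondrial import channel (1.98 ± 0.549). The locus AT1G08643, with 92.57, 43.61 and 56.78 FPKM in white-light pif7, is listed at 0 in all 3 shaded pif7 libraries, and ATMG01380 is listed at 0 in all 3 white-light pif7 libraries and at 36.84, 77.79 and 43.82 in shade. Shade changed 8312 genes in pif7, 5715 higher and 2597 lower, or 3423 higher and 3681 lower after rescaling. The difference from WT was called for 1167 genes, 598 larger and 569 smaller, and 289 and 751 after rescaling; at 1 log2 unit or more they number 92 and 307.

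**Figure D2:**
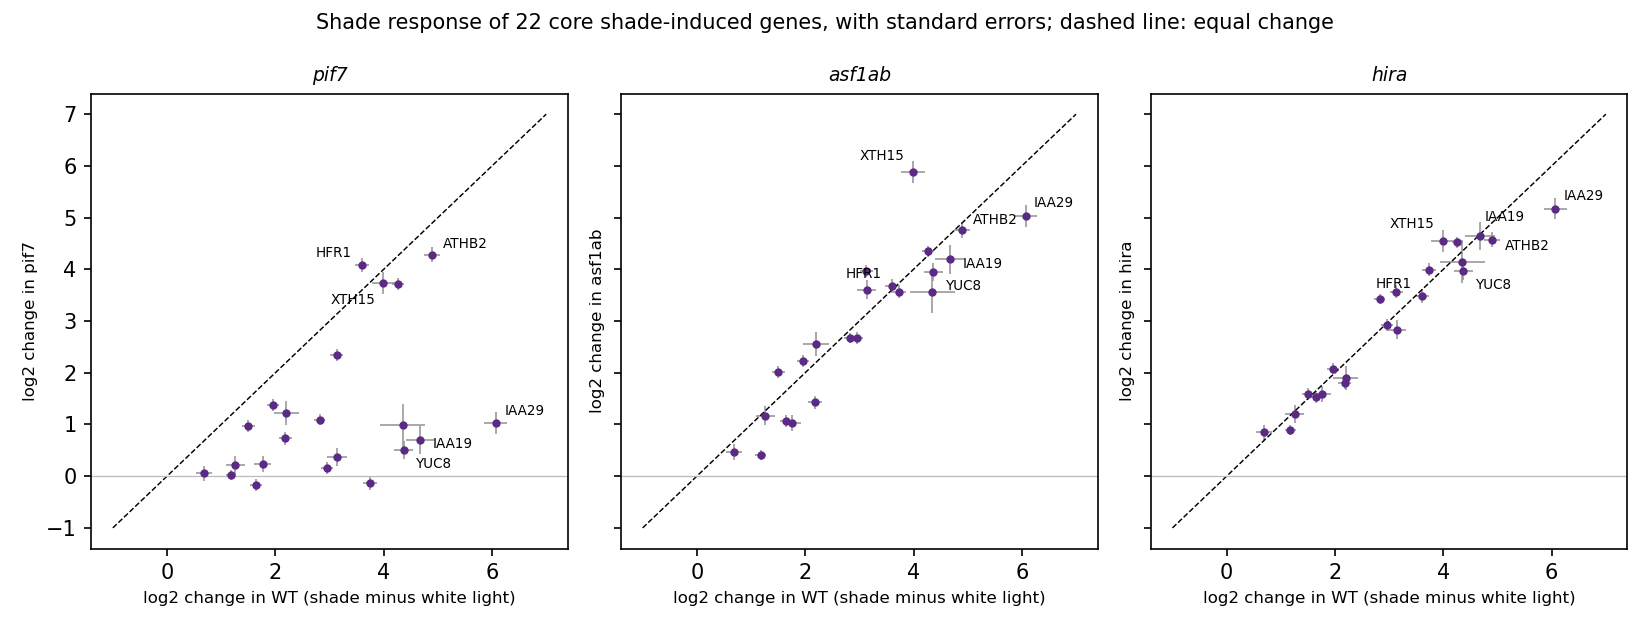
Shade response of the 22 core shade-induced genes in each mutant (vertical axis, log2) against WT (horizontal axis, log2), with standard errors as bars and a dashed line of equal change. IAA29 reads 6.07 in WT and 1.03 in pif7.

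By list, the core shade-induced genes had 13 of 22 risen in pif7, 14 adjusted over the list alone (median 0.85, rescaled 0.73, adjusted p = 3.34e-06, and adjusted p = 0.0580 with an estimated correlation). Against WT 16 of the 22 responded less, 20 with 1 responding more adjusted over the list alone, including HAT2 (-2.79 ± 0.158), CKX5 (-2.77 ± 0.253), ATHB4 (-1.45 ± 0.172) and HAT3 (-1.16 ± 0.135); median -1.303, rescaled -1.40, adjusted p = 2.11e-35. SAUR genes responded less in 24 of 28, 25 adjusted over the list alone (median -2.11, rescaled -2.22, adjusted p = 2.39e-53), with SAUR28 at -3.68 ± 0.327 and SAUR10 at -3.32 ± 0.216. Within pif7 7 SAUR genes rose and 5 fell, and the median of 0.014 turns to -0.089 after rescaling. Aux/IAA and GH3 genes responded less in 20 of 30 and more in 1, or 21 and 2 adjusted over the list alone (median -1.07, rescaled -1.13, adjusted p = 4.32e-33). Auxin biosynthesis and transport genes did so in 7 of 12 and more in 2, or 8 and 2 adjusted over the list alone (median -1.02, rescaled -1.104, adjusted p = 1.93e-11). Gibberellin genes responded less in 4 of 13, 5 with 2 responding more adjusted over the list alone, GA20OX1 by -2.41 ± 0.251 (median -0.288, rescaled -0.369, adjusted p = 0.00163). Ethylene genes did so in 3 of 9, 4 adjusted over the list alone, ACS4 by -2.65 ± 0.186 (median -0.753, rescaled -0.844, adjusted p = 5.31e-08). Cell wall loosening genes responded less in 6 of 23, 9 with 3 more adjusted over the list alone, XTH17 by -2.27 ± 0.396 (median -0.455, rescaled -0.575, adjusted p = 4.23e-05, and adjusted p = 0.0542 with an estimated correlation). In the brassinosteroid list BEE1 (-1.73 ± 0.143), BAS1 (-1.59 ± 0.188) and BRI1 (-0.71 ± 0.151) responded less, 3 of 15, or 4 and 1 more adjusted over the list alone. The median of 0.012, -0.10 after rescaling, differs in sign from camera (adjusted p = 0.0475, and adjusted p = 0.419 with an estimated correlation). KAT1, the only called member of 6 stomatal genes, also 1 adjusted over the list alone, differed by -2.13 ± 0.163 (list median -0.104, rescaled -0.186, adjusted p = 0.0490, and adjusted p = 0.399 with an estimated correlation).

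Photosynthesis and division genes fell in shaded pif7. LHCB1.1, 1 of several near-identical antenna protein genes, fell by -1.52 ± 0.239, LHCB3 by -1.16 ± 0.246 and 18 of 24 photosynthesis genes in all, 20 adjusted over the list alone (median -0.638, rescaled -0.783, adjusted p = 1.97e-10, and adjusted p = 0.352 with an estimated correlation). Their response was lower than in WT for 12 of 24, 17 adjusted over the list alone (median -0.635, rescaled -0.756, adjusted p = 5.24e-16, and adjusted p = 0.0542 with an estimated correlation). The mitosis genes CDKB1;1 (-0.79 ± 0.213) and KNOLLE (-0.73 ± 0.186) were among 9 of 13 that fell, 11 adjusted over the list alone (rescaled median -0.692, adjusted p = 7.74e-05, and adjusted p = 0.651 with an estimated correlation). KNOLLE, AUR1 and CYCB2;2 also differed from WT, 3 of 13, or 7 adjusted over the list alone (median -0.699, rescaled -0.778, adjusted p = 1.90e-07, and adjusted p = 0.179 with an estimated correlation). PCNA1 (-0.85 ± 0.224) and MCM2 (-0.57 ± 0.143) were among 7 of 12 replication genes that fell, 8 adjusted over the list alone (adjusted p = 0.000139, and adjusted p = 0.651 with an estimated correlation). Brassinosteroid genes rose in 13 of 15 and fell in 1, the same adjusted over the list alone, IBH1 by 1.75 ± 0.152 and the synthesis gene CPD by 1.49 ± 0.101 (median 0.664, rescaled 0.529, adjusted p = 1.96e-05, and adjusted p = 0.188 with an estimated correlation). Plastid-encoded genes had 0 of 75 called and 0 adjusted over the list alone, at a median of -0.106, rescaled -0.241 (camera adjusted p = 0.0188, and adjusted p = 0.827 with an estimated correlation). Of jasmonate genes ST2A (-3.37 ± 0.588), LOX2 (-2.66 ± 0.581) and AOS (-1.07 ± 0.211) responded less than in WT, 3 of 17, or 5 adjusted over the list alone (median -0.432, rescaled -0.548, adjusted p = 4.23e-05, and adjusted p = 0.399 with an estimated correlation). The morning clock genes CCA1 and LHY fell in pif7 by -1.35 ± 0.146 and -0.997 ± 0.108, while camera did not call the clock list there.

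Was shade sensed in asf1ab as in WT? XTH15 rose more than in WT, by 5.88 ± 0.215, a difference of 1.89 ± 0.305 (adjusted p = 0.00663). FLP1 rose by 5.43 ± 0.283, IAA29 by 5.04 ± 0.210, ATHB2 by 4.76 ± 0.145 and PIL1 by 4.35 ± 0.110, with none of these 4 called different from WT. CAF1a, a deadenylase gene, went from 29.3 ± 1.34 to 12.2 ± 1.11 FPKM in asf1ab and from 9.92 ± 2.78 to 22.2 ± 4.63 in WT, a difference of -2.30 ± 0.212 (adjusted p = 2.58e-05). Lower responses were also called for AT5G51190 (-4.86 ± 0.652), the EF-hand gene AT4G27280 (-2.23 ± 0.278), the AP2/ERF gene AT2G22200 (-2.02 ± 0.403), the cold-response factor gene CBF2 (-1.91 ± 0.299) and ERF5 (-1.87 ± 0.381). Higher responses came from AT5G50600, a seed oil body dehydrogenase gene with a near-identical copy (2.503 ± 0.551), the polynucleotide phosphorylase gene AT5G14580 (1.60 ± 0.281), the ERF gene AT5G61590 (1.53 ± 0.311), the BTB/TAZ gene BT5 (1.304 ± 0.254) and ICME-LIKE2 (1.23 ± 0.245). In asf1ab itself XTH31 fell by -3.79 ± 0.229 and LEA3, a late embryogenesis abundant gene, by -3.63 ± 0.267; AT2G03895 is listed at 0 in the 3 shaded libraries after 29.51, 9.48 and 21.48 FPKM in white light, and AT1G09557 rose by 4.57 ± 1.12. Shade changed 5944 genes, 3601 higher and 2343 lower, or 2974 and 2930 after rescaling, and 88 differed from WT, 33 higher and 55 lower.

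The core shade-induced genes rose in 22 of 22 in asf1ab, 22 adjusted over the list alone (median 3.12, adjusted p = 8.30e-29). Their response differed from WT upward for XTH15 and PAR1 (0.83 ± 0.171) and downward for HAT3 (-0.77 ± 0.135), 2 and 1 of 22, or 3 and 5 adjusted over the list alone (median -0.161, adjusted p = 0.0554). Aux/IAA and GH3 genes rose in 20 of 30 and fell in 2, or 22 and 2 adjusted over the list alone (adjusted p = 5.18e-12). They responded less than in WT for GH3.5 (-1.24 ± 0.233), GH3.6 (-1.15 ± 0.162) and IAA6 (-1.04 ± 0.213), 3 of 30, or 9 adjusted over the list alone (median -0.256, adjusted p = 2.21e-10). SAUR genes rose in 22 of 28 and fell in 2, or 23 and 2 adjusted over the list alone (adjusted p = 2.68e-17). SAUR9 responded less by -1.12 ± 0.232, 1 of 28, or 8 adjusted over the list alone (median -0.333, adjusted p = 4.40e-08, and adjusted p = 0.195 with an estimated correlation). Auxin biosynthesis and transport had 8 risen and 3 fallen of 12, 9 and 3 adjusted over the list alone (adjusted p = 0.00119, and adjusted p = 0.134 with an estimated correlation). No member differed from WT, 1 did adjusted over the list alone, and the median was -0.185 (adjusted p = 0.00425, and adjusted p = 0.223 with an estimated correlation). No gibberellin gene differed from WT over all genes, 3 did adjusted over the list alone, with GA20OX2 at -1.004 ± 0.249 (median -0.255, adjusted p = 0.000102). Cell wall loosening genes differed in 1 upward and 4 downward of 23, 2 and 8 adjusted over the list alone, the expansin genes EXPA8 by -1.68 ± 0.284 and EXPA11 by -1.58 ± 0.336 (median -0.421, adjusted p = 1.11e-05, and adjusted p = 0.0764 with an estimated correlation). Brassinosteroid genes rose in 10 of 15, 10 adjusted over the list alone (adjusted p = 1.18e-06, and adjusted p = 0.0522 with an estimated correlation). Ethylene genes rose in 6 of 9 with ACS6 fallen, the same adjusted over the list alone (adjusted p = 0.00284, and adjusted p = 0.152 with an estimated correlation). Plastid-encoded genes fell in 11 of 75, 6 adjusted over the list alone (median -0.351, adjusted p = 0.00284, and adjusted p = 0.679 with an estimated correlation). Against WT several lists passed camera without a called member: photosynthesis (median -0.285, adjusted p = 6.47e-05, and adjusted p = 0.436 with an estimated correlation), the stomatal list (-0.218, adjusted p = 0.0371, and adjusted p = 0.434 with an estimated correlation) and plastid-encoded genes (-0.136, adjusted p = 0.0371, and adjusted p = 0.782 with an estimated correlation). Jasmonate genes (median -0.161, adjusted p = 0.0327, and adjusted p = 0.690 with an estimated correlation) and mitochondrion-encoded genes (0.351, adjusted p = 0.0140, and adjusted p = 0.434 with an estimated correlation) each had 1 member called when adjusted over the list alone.

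Which genes responded differently in hira? MYC2, the central jasmonate bHLH gene, fell from 22.8 ± 1.04 to 4.32 ± 2.17 FPKM in hira and read 12.7 ± 5.23 and 16.1 ± 4.14 in WT, a difference in response of -2.63 ± 0.446 (adjusted p = 0.00484). CAF1a fell from 67.0 ± 6.54 to 18.8 ± 2.59 FPKM in hira (difference from WT -2.88 ± 0.212, adjusted p = 5.53e-07), and CBF2 went from 8.87 ± 3.07 to 3.29 ± 0.563 (difference -2.82 ± 0.299). AT5G51190 and AT4G27280 also responded less, by -4.75 ± 0.652 and -2.94 ± 0.278. AT2G22880, a VQ-motif gene, read 10.81, 17.08 and 10.05 FPKM in white-light hira and is listed at 0 in the 3 shaded libraries. Responses were larger in hira for AT5G53895 (2.07 ± 0.436), AT4G34950 (1.79 ± 0.410), the fibrillin gene FIB (1.76 ± 0.396), AT5G61590 (1.66 ± 0.311) and AT1G72416 (1.62 ± 0.358). AT4G07975 is listed at 0 in white-light hira and at 2.88, 3.33 and 3.36 FPKM in shaded hira. Shade markers rose in hira: FLP1 by 5.29 ± 0.283 (difference from WT -0.94 ± 0.400, adjusted p = 0.213), IAA29 by 5.18 ± 0.210 (difference -0.89 ± 0.298, adjusted p = 0.123), IAA19 by 4.65 ± 0.274, ATHB2 by 4.57 ± 0.145 and YUC8 by 3.98 ± 0.173. AT1G09557, listed at 0 in white-light hira, read 23.72, 24.63 and 29.59 FPKM in shade, while AT5G04175 and U1.2 are listed at 0 in shaded hira. Shade changed 6807 genes in hira, 4980 higher and 1827 lower, or 2701 and 2843 after rescaling. The difference from WT was called for 247 genes, 116 higher and 131 lower, and 55 and 208 after rescaling.

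**Figure D3:**
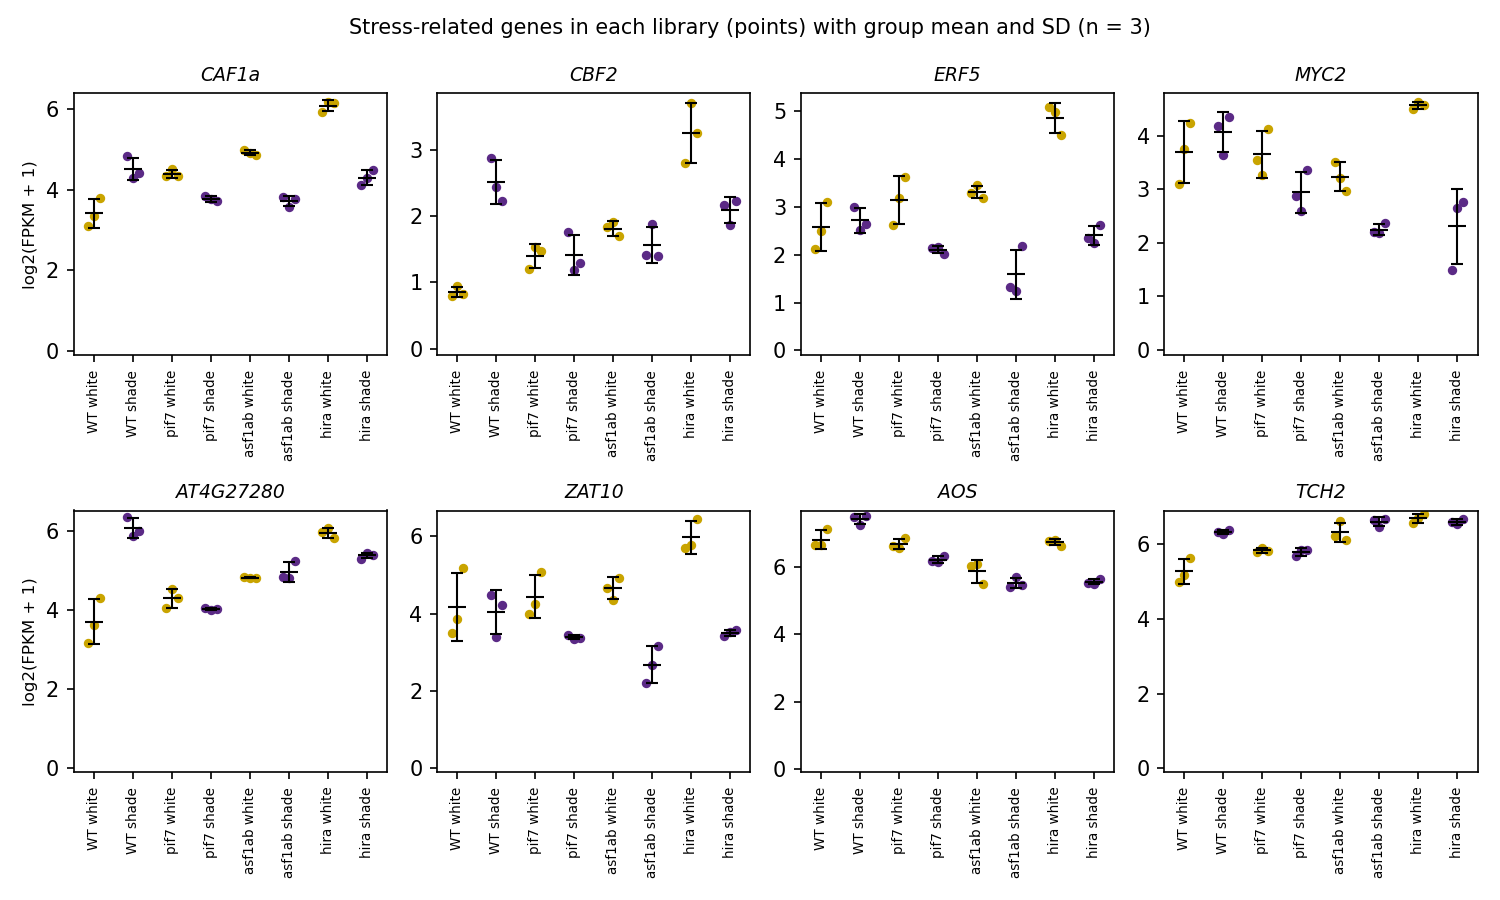
Values of log2(FPKM + 1) for CAF1a, CBF2, ERF5, MYC2, AT4G27280, ZAT10, AOS and TCH2 in the 8 groups. Points are single libraries, and bars are the group mean of the log2 values with its SD (n = 3). Before the transformation, the mean of CAF1a is 67.0 FPKM in white-light hira and 9.92 in white-light WT.

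Among the lists in hira the core shade-induced genes rose in 22 of 22, 22 adjusted over the list alone (median 3.18, rescaled 3.03, adjusted p = 1.52e-28). Only BEE1 differed from WT (0.61 ± 0.143), 1 also adjusted over the list alone (median -0.085, rescaled -0.190, adjusted p = 0.117). SAUR genes rose in 25 of 28 and fell in 1, or 25 and 2 adjusted over the list alone (rescaled median 2.497, adjusted p = 5.21e-20). Aux/IAA and GH3 genes rose in 23 of 30 and fell in 1, or 24 and 1 adjusted over the list alone (rescaled median 0.870, adjusted p = 1.72e-12). IAA30 (-1.33 ± 0.311) and GH3.5 (-1.03 ± 0.233) responded less than in WT, 2 of 30, or 5 adjusted over the list alone (median -0.173, rescaled -0.292, adjusted p = 6.23e-07). Auxin biosynthesis and transport had 9 risen and 2 fallen of 12, or 9 and 3 adjusted over the list alone (adjusted p = 0.00049, and adjusted p = 0.116 with an estimated correlation). Brassinosteroid genes had 13 and 1 of 15 in both counts, also adjusted over the list alone (adjusted p = 4.77e-07), ethylene genes 5 and 1 of 9, or 6 and 1 adjusted over the list alone (adjusted p = 0.00904, and adjusted p = 0.260 with an estimated correlation). Of the ethylene genes ACS11 responded less than in WT by -0.88 ± 0.208, 1 of 9, or 2 adjusted over the list alone (median -0.232, rescaled -0.365, adjusted p = 0.0115, and adjusted p = 0.302 with an estimated correlation). No gibberellin gene differed over all genes and 1 adjusted over the list alone, GA20OX2 reading -0.94 ± 0.249 (median -0.264, rescaled -0.395, adjusted p = 0.000183). Of 23 cell wall genes 0 differed in both counts, adjusted over the list alone included, at a median of -0.020, rescaled -0.155 (adjusted p = 0.0416, and adjusted p = 0.449 with an estimated correlation). Photosynthesis genes fell in 11 of 24, 12 adjusted over the list alone, LHCB1.1 by -1.105 ± 0.239 and the tetrapyrrole gene HEMA1 by -0.69 ± 0.087 (rescaled median -0.634, adjusted p = 1.65e-07, and adjusted p = 0.260 with an estimated correlation). The antenna copies LHCB1.2 (-1.70 ± 0.346) and LHCB1.1 (-1.58 ± 0.338) responded less than in WT, 2 of 24, or 16 with 2 responding more adjusted over the list alone (median -0.549, rescaled -0.687, adjusted p = 9.40e-13, and adjusted p = 0.235 with an estimated correlation).

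Some defence and stress genes fell in shaded hira. WRKY33 (-2.77 ± 0.410), WRKY40 (-2.73 ± 0.527), CBP60G and PAD4 were among 5 of 13 salicylic acid and immunity genes that fell, 5 adjusted over the list alone (rescaled median -0.687, adjusted p = 8.33e-05, and adjusted p = 0.341 with an estimated correlation). Their response was not called different from WT for any member, and for 2 adjusted over the list alone (median -0.455, rescaled -0.579, adjusted p = 0.000101, and adjusted p = 0.429 with an estimated correlation). Jasmonate genes had ST2A risen and MYC2, AOS (-1.17 ± 0.149) and LOX3 fallen, 1 and 3 of 17, the same adjusted over the list alone (adjusted p = 0.00443, and adjusted p = 0.499 with an estimated correlation). MYC2 and AOS (-1.78 ± 0.211) responded less than in WT, 2 of 17, or 3 adjusted over the list alone (median -0.859, rescaled -0.941, adjusted p = 4.79e-09, and adjusted p = 0.302 with an estimated correlation). The zinc-finger gene ZAT10 (-2.33 ± 0.518) and TCH2 (-1.15 ± 0.187) responded less among 12 heat shock, touch and handling genes, 2, or 5 with 2 more adjusted over the list alone. The list median is 0.068, -0.018 after rescaling, while camera ranks the list downward (adjusted p = 0.0160, and adjusted p = 0.607 with an estimated correlation). Plastid-encoded genes fell in 30 of 75, 34 adjusted over the list alone, ATCG00360 by -1.73 ± 0.402 (rescaled median -1.03, adjusted p = 7.97e-14, and adjusted p = 0.260 with an estimated correlation). They differed from WT at a median of -0.695, rescaled -0.833, with 0 called in either count, adjusted over the list alone included (adjusted p = 3.72e-13, and adjusted p = 0.302 with an estimated correlation). Clock genes had LUX among 3 risen and PRR9 (-1.35 ± 0.243) among 6 fallen of 15, the same adjusted over the list alone (adjusted p = 0.0315, and adjusted p = 0.490 with an estimated correlation). PCNA1, MCM7 and MCM6 fell, 3 of 12 replication genes, or 2 adjusted over the list alone (adjusted p = 0.00133, and adjusted p = 0.418 with an estimated correlation). AUR2 fell by -0.61 ± 0.164, 1 of 13 mitosis genes, 1 adjusted over the list alone (adjusted p = 0.00133, and adjusted p = 0.430 with an estimated correlation). None differed from WT in either count, at a median of -0.325, rescaled -0.452 (adjusted p = 2.33e-06, and adjusted p = 0.302 with an estimated correlation).

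How much of the WT response remained in each mutant, and was it shared? Genes induced in WT were chosen without a WT replicate, 1820 to 2270 genes, and responded by a median log2 of 0.580 ± 0.076 in the left-out WT replicate. The mutant medians were 0.522 ± 0.033 in pif7, 0.607 ± 0.045 in asf1ab and 0.596 ± 0.039 in hira, or 0.906 ± 0.061, 1.05 ± 0.061 and 1.03 ± 0.065 of the WT value (SD of 3 repeats). Each repeat used all libraries of a mutant, so the SD of its median comes from the choice of genes, not from its libraries. After rescaling the shares of the WT value are 0.690, 0.981 and 0.818, given without a spread, so that hira reads below WT and asf1ab near it. For 1315 to 1693 repressed genes the ratios were 0.776 ± 0.059, 1.03 ± 0.102 and 0.734 ± 0.064, with no rescaled share given here. The whole distribution shifted upward with shade by a median of 0.119 in pif7 and 0.137 in hira, against 0.008 in WT. Such a shift makes falls smaller, so the low ratios of pif7 and hira do not by themselves show weaker repression. The differences in shade response from WT correlated across genes at 0.439 for pif7 and asf1ab, 0.512 for pif7 and hira and 0.563 for asf1ab and hira, where the shared WT libraries alone give 0.496, 0.498 and 0.496 in simulation. Covariance exceeded that from the shared WT libraries by 0.0244, 0.0490 and 0.0302 in the same order. Lower responses such as those of CAF1a, CBF2 and AT5G51190 were called in both pif7 and asf1ab for 28 genes, in pif7 and hira for 49 and in asf1ab and hira for 26, against 1.60, 3.90 and 0.400 for independent calls. Higher responses were shared by 5, 45 and 6 genes in the same order, against 1, 3.6 and 0.2; after rescaling the higher calls drop to 289 in pif7 and 55 in hira. WT has too few libraries to be split, so the excess can still hold the noise of the shared controls.

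What differs between pif7 and WT before shade? MRD1, a gene first named for its response in the mto1 mutant, read 29.6 ± 1.64 FPKM in pif7 and 0.157 ± 0.238 in WT (4.75 ± 0.198 log2, adjusted p = 1.02e-11). The assembled locus MSTRG.19097 was higher by 2.02 ± 0.167, and AT3G05955, AT2G01422 and PDF1.3 by 2.35 ± 0.273, 1.85 ± 0.220 and 3.04 ± 0.613. The anthocyanin enzyme genes LDOX (1.81 ± 0.391), AT4G14090 (1.68 ± 0.312) and AT5MAT (1.44 ± 0.263) were higher. Lower genes besides PIF7 were AT4G13580 (-2.80 ± 0.322), ATPMEPCRD (-2.51 ± 0.357), AT4G04223 (-2.26 ± 0.199), AT3G55230 (-1.99 ± 0.246), AT2G28671 (-1.74 ± 0.228), the peroxidase gene AT5G66390 (-1.72 ± 0.254) and the Casparian strip gene CASP1 (-1.58 ± 0.231). CASP1 is 1 of 5 root markers and KNAT1 (-0.96 ± 0.187) 1 of 6 shoot meristem markers, while LHY was higher by 0.56 ± 0.108. Few genes differed, 76 in all, 21 higher and 55 lower. SAUR genes had none of 28 called, 3 higher and 1 lower adjusted over the list alone (median 0.213, adjusted p = 0.000431, and adjusted p = 0.733 with an estimated correlation). Photosynthesis (median 0.186, adjusted p = 0.000357, and adjusted p = 0.904 with an estimated correlation), stomatal (0.194, adjusted p = 0.0282, and adjusted p = 0.733 with an estimated correlation) and plastid-encoded genes (0.185, adjusted p = 0.0282, and adjusted p = 0.962 with an estimated correlation) had none called, adjusted over the list alone included.

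Seed storage messages set asf1ab apart in white light. SESA5, a 2S albumin gene, read 72.9 ± 55.3 FPKM in asf1ab and 0.0433 ± 0.0379 in WT (5.81 ± 0.401 log2, adjusted p = 8.55e-09). CRA1 (5.78 ± 0.505), SESA2 (5.51 ± 0.377) and the defensin gene LCR67 (5.20 ± 0.547) were higher as well. CRU3, a 12S globulin gene, is listed at 0 in white-light WT and at 17.75, 65.16 and 51.39 FPKM in asf1ab. SESA1 reads 11.68, 52.30 and 27.00 and SESA3 10.19, 47.31 and 24.56 FPKM in asf1ab, each listed at 0 in white-light WT. Besides these storage genes, AT3G02790 reads 23.73, 52.47 and 32.39 FPKM in asf1ab and is listed at 0 in white-light WT. AT3G02790 was also higher in hira, by 3.899 in white light and 4.132 in shade. Of 13 seed maturation genes 12 were higher, 12 adjusted over the list alone (median 2.64, adjusted p = 4.39e-17, and adjusted p = 0.0941 with an estimated correlation). Lower genes were the glutathione transferase gene GSTU24 (-3.85 ± 0.916), the cytochrome P450 gene CYP81D11 (-3.72 ± 1.02), DIN11 (-3.69 ± 1.01), PDF1.2A, which has a near-identical copy (-3.61 ± 0.789), AT3G09160 (-3.55 ± 0.183), the oxygenase gene AT2G38240 (-3.53 ± 0.803) and AT4G11410 (-3.47 ± 0.243). AT1G09333, at 13.44, 28.89 and 69.68 FPKM in white-light WT, is listed at 0 in all 6 asf1ab libraries. Jasmonate genes were lower in 15 of 17, 16 adjusted over the list alone, the vegetative storage protein genes VSP2 by -2.50 ± 0.448 and VSP1 by -2.27 ± 0.365 (median -1.38, adjusted p = 6.78e-07, and adjusted p = 0.640 with an estimated correlation). Among markers of other tissues KNAT1 (-1.34 ± 0.187), STM (-0.95 ± 0.115), TIP2;3 (-1.34 ± 0.319) and CASP1 (-1.25 ± 0.231) were lower, single members of lists that camera did not call. Photosynthesis genes were higher in 7 of 24, 13 adjusted over the list alone, the RBCS2B copy by 1.51 ± 0.321 (median 0.406, adjusted p = 2.69e-08, and adjusted p = 0.640 with an estimated correlation). Histone genes had 4 higher and 2 lower of 20, or 6 and 2 adjusted over the list alone, the H3 genes HTR3 by 0.70 ± 0.151 and HTR4 by 0.61 ± 0.085 (median 0.093, adjusted p = 0.0437, and adjusted p = 0.640 with an estimated correlation). SAUR genes had 5 higher and 3 lower of 28, also adjusted over the list alone (adjusted p = 0.0323, and adjusted p = 0.821 with an estimated correlation). Plastid-encoded genes had 7 of 75 higher and 0 adjusted over the list alone (median 0.410, adjusted p = 1.04e-05, and adjusted p = 0.821 with an estimated correlation), while plastid transcripts take 2.31% of replicate 1 and 1.12 and 0.99% of replicates 2 and 3. In all 4225 genes differed, 1197 higher and 3028 lower, or 1844 and 2312 after rescaling.

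**Figure D4:**
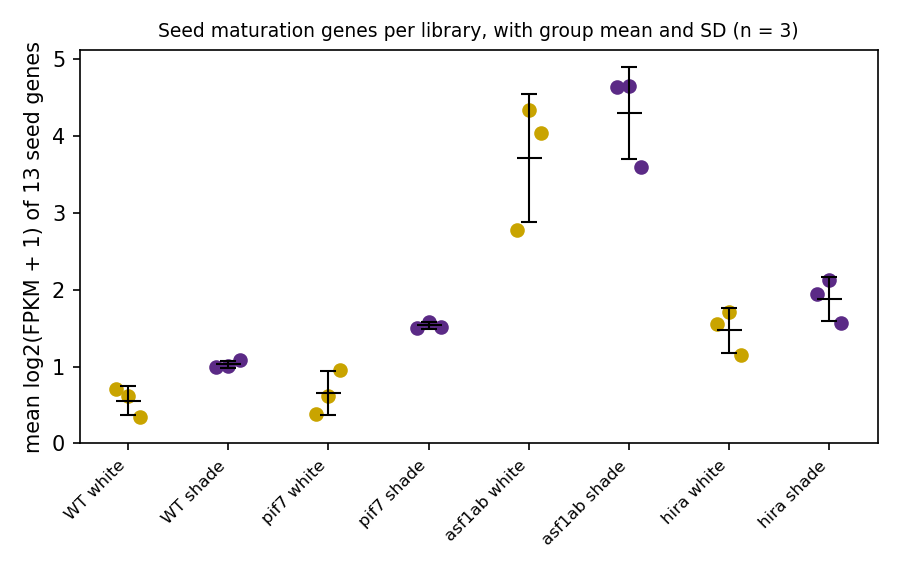
Mean log2(FPKM + 1) of 13 seed maturation genes in the 8 groups, with points for single libraries and bars for the group mean with its SD (n = 3). The lowest asf1ab library reads 2.77 and the highest library of the other genotypes 2.13.

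What differs between hira and WT before shade? CAF1a was higher in hira by 2.66 ± 0.150 (adjusted p = 8.01e-10), CBF2 by 2.40 ± 0.211, ERF5 by 2.29 ± 0.269, ZAT10 by 1.79 ± 0.367 and TCH2 by 1.42 ± 0.132. The white-light values of CAF1a, CBF2 and ERF5 were looked up after their shade responses were seen. MRD1 was higher by 4.54 ± 0.198, reading 25.6 ± 2.81 FPKM. The neighbours AT3G29631 (5.10 ± 0.337) and AT3G29639 (4.64 ± 0.186) were higher in hira, as were AT3G05845 (5.08 ± 0.398) and the assembled locus MSTRG.13930 (3.93 ± 0.153). AT1G75945 (4.54 ± 0.274) and AT5G35480 (3.998 ± 0.369) were higher too. AT1G64795 is listed at 0 in all WT and pif7 libraries and at 30.42, 51.22 and 70.29 FPKM in white-light hira. Lower genes were the lipid-transfer gene EARLI1 (-3.595 ± 0.831) and its relative AT4G12490 (-3.55 ± 0.827), U4.10 (-3.24 ± 0.778), AT3G04230 (-2.88 ± 0.195), BGLU11 (-2.58 ± 0.630), the jasmonate-induced oxygenase gene JRG21 (-2.56 ± 0.487), AT4G11410 (-2.47 ± 0.243) and AIG1 (-2.42 ± 0.489). Plastid-encoded genes were higher in 24 of 75, 36 adjusted over the list alone, ATCG00300 by 3.90 ± 1.01 (median 1.05, rescaled 1.14, adjusted p = 1.80e-27, and adjusted p = 0.195 with an estimated correlation). Photosynthesis genes were higher in 8 of 24, 15 adjusted over the list alone, the LHCB1.2 copy by 1.18 ± 0.245 (rescaled median 0.531, adjusted p = 8.08e-13, and adjusted p = 0.232 with an estimated correlation). Seed maturation genes were higher in 6 of 13, 6 adjusted over the list alone, CRA1 by 2.11 ± 0.505 (rescaled median 0.841, adjusted p = 8.81e-08, and adjusted p = 0.264 with an estimated correlation). Cell wall genes had XTH22 (1.36 ± 0.241) and EXPB1 higher, 2 of 23, also adjusted over the list alone (rescaled median 0.444, adjusted p = 8.07e-06, and adjusted p = 0.195 with an estimated correlation). Mitosis genes had 1 of 13, KNOLLE (0.60 ± 0.186), or 2 adjusted over the list alone (rescaled median 0.472, adjusted p = 2.00e-07, and adjusted p = 0.303 with an estimated correlation). Jasmonate genes were lower in 5 of 17, or 10 with 1 higher adjusted over the list alone, VSP1 by -1.3 ± 0.365 (rescaled median -0.738, adjusted p = 0.00686, and adjusted p = 0.738 with an estimated correlation). Mitochondrion-encoded genes had 0 of 28 called, adjusted over the list alone included (rescaled median 0.10, adjusted p = 0.00686, and adjusted p = 0.465 with an estimated correlation). In all 2228 genes differed, 500 higher and 1728 lower, and 754 and 667 after rescaling, so the balance of directions turns with the scaling. Replicate 3 of white-light hira lies nearer to WT replicates 2 and 3 (SD of log2 differences 0.382 and 0.396) than to hira replicates 1 and 2 (0.479 and 0.536), and without it 4248 genes were called. Without replicate 1 or 2 the count is 839 or 1253, and with only the WT and hira white-light libraries in the fit 183. The position of replicate 3 is not particular to hira. Replicate 3 of white-light pif7 also lies nearer to WT replicates 2 and 3 (0.428 and 0.431) than to pif7 replicates 1 and 2 (0.467 and 0.456).

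The asf1ab and hira changes in white light overlapped most. Their differences from WT correlated at 0.664, where shared WT libraries give 0.50, and covariance exceeded simulation by 0.116. Both mutants were higher for 308 genes and lower for 1179, against 31.3 and 273.6 for independent calls, with AT4G11410 and VSP1 lower in both and MSTRG.19097 higher in both. The counts for independent calls take no account of the shared WT libraries. Nor do they allow for the shift of asf1ab and hira below WT, by medians of -0.067 and -0.117. After rescaling only 667 genes are lower in hira at all, so the 1179 shared lower genes hold only without it. For pif7 the correlation was 0.322 with asf1ab and 0.381 with hira, below the simulated 0.502 and 0.508, though the covariance exceeded simulation by 0.0147 and 0.0133. MRD1 was among 7 genes higher in both pif7 and hira, and 22 were lower in both; pif7 and asf1ab shared 9 higher and 38 lower genes.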

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

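The counts, lists and single genes given here were flagged because a mutant's shade response differed from that of WT in a test of the difference itself. The seed and neighbour patterns are instead differences from WT in white light and in both lights. The label exchanges and the ribosomal RNA test were written before their values were seen. The other tests of the 3 patterns, and the patterns themselves, were chosen after the results were seen.

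The first pattern is a lower shade response in hira: 92 genes were called at -1 log2 or below, with a median of -1.55, CAF1a and CBF2 among them, and also antenna and auxin genes such as LHCB1.1 and IAA30. A larger share of ribosomal RNA in white-light hira predicts that rescaling removes the difference, and the rescaled median is -1.67. The scaling factors lie between 0.8975 and 1.119, so rescaling could not remove a difference of this size, and the test decides nothing. Factors in this range are too small to produce such a difference by scaling alone. If 1 or 2 disturbed white-light hira libraries carried it, a library left out of the choice of genes would show no excess over WT. On the 67, 56 and 159 genes chosen without replicates 1, 2 and 3 these replicates read 0.998, 1.26 and 0.545 higher (SD 0.363). The lowest does not settle the point, and the WT white-light libraries stayed in the choice of genes, which by itself favours an excess. Ribosomal RNA takes 8.32, 7.27 and 3.22% of the summed FPKM in replicates 1, 2 and 3. Unusual WT libraries predict the same response in all mutants. On these 92 genes the median shade response was 0.309 in WT, -0.37 in pif7, -0.55 in asf1ab and -1.221 in hira. The other mutants thus also lie below WT, but the genes were chosen on the same WT libraries, which by itself favours that. By gene, hira lies below the mean of pif7 and asf1ab by a median of -0.744. Choosing genes for a low response in hira by itself favours such a gap, so this explanation stays open. Handling of the whole white-light hira group before harvest stays possible beside an effect of the genotype.

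For the second pattern, seed maturation transcripts higher in asf1ab, seed material in a few libraries was tested: all 6 asf1ab libraries lie above the 18 others (lowest mean log2 2.77, highest other 2.13), which argues against it. Retained seed or delayed germination would bring all abundant seed transcripts. That 92.3% of the tested members (12 of 13) were called higher is the observation that defined the pattern, so it lends this no support, and it stays open beside a change of transcription.

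The third pattern is that genes strongly changed in hira in both lights lie near each other. A chromosome segment of another strain or a linked insertion predicts such groups: 12 of 33 genes have another within 10 tested loci (5 places, at most 3 genes each), where 10000 random draws give a median of 0 and an upper bound of 4. In asf1ab, however, 22 of 98 do against a median of 10 and an upper bound of 18, and several hira groups are related gene copies such as EARLI1 with AT4G12490, so this could not be told from grouping of related genes. In pif7 0 of 3 genes had such a neighbour.

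Exchanging labels tests whether chance can be excluded. For shade in WT, pif7, asf1ab and hira and for pif7, asf1ab and hira in white light only 10 splits exist, too few to exclude chance. The real count was matched by 1 split, itself, with 5043, 8312, 5944, 6807, 76, 4225 and 2228 genes against highest other counts of 0, 3, 7, 0, 2, 35 and 176. For the difference in shade response of pif7, 4 of 100 splits drawn from 200 reach the real 1167 genes (highest other 3134). For asf1ab 10 of 100 drawn reach 88 (highest other 2685) and for hira 8 reach 247 (highest other 3864), so these counts do not exclude chance in asf1ab and hira. Every other split that reaches a real count exchanges unequal numbers of libraries in the 2 lights, and so carries the difference between genotypes into the result: the high counts reflect this structure of the samples, and the shares are no clean test of chance in any of the 3 mutants. Of the 48, 41 and 40 splits that exchange equal numbers in pif7, asf1ab and hira, a choice made after the counts were seen, 0 reach the real count, with at most 3, 1 and 1 genes. Such splits mix genotypes within each group, which widens the spread and by itself lowers their counts. They are therefore no clean test of chance either.

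The remaining flagged values are given without explanation. Of the 12, 10 and 10 lists called for the differences in pif7, asf1ab and hira, 6, 2 and 2 keep the call with an estimated correlation, and the medians of brassinosteroid genes in pif7 and of heat shock, touch and handling genes in hira run against the direction of camera. In pif7 minus WT, list medians of the difference in log2 were -1.303 for core shade-induced genes, -1.022 for auxin biosynthesis and transport, -1.069 for Aux/IAA and GH3, -2.107 for SAUR, 0.012 for brassinosteroid, -0.288 for gibberellin, -0.753 for ethylene, -0.455 for cell wall loosening, -0.635 for photosynthesis, -0.699 for mitosis, -0.432 for jasmonate and -0.104 for stomatal genes. In asf1ab minus WT they were -0.185 for auxin biosynthesis and transport, -0.256 for Aux/IAA and GH3, -0.333 for SAUR, -0.255 for gibberellin, -0.421 for cell wall loosening, -0.285 for photosynthesis, -0.161 for jasmonate, -0.218 for stomatal, -0.136 for plastid-encoded and 0.351 for mitochondrion-encoded genes. In hira minus WT they were -0.173 for Aux/IAA and GH3, -0.264 for gibberellin, -0.232 for ethylene, -0.020 for cell wall loosening, -0.549 for photosynthesis, -0.325 for mitosis, -0.455 for salicylic acid and immunity, -0.859 for jasmonate, 0.068 for heat shock, touch and handling and -0.695 for plastid-encoded genes.

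Single genes differed in pif7 minus WT by 3.791 (U4.10), 2.506 (AT1G07567), 2.433 (CRA1), 2.257 (AT3G20340), 2.065 (AT2G34317), 1.985 (TOM7-2), -5.045 (IAA29), -4.666 (FLP1), -4.611 (AT5G51190), -4.585 (PDF1.3), -4.327 (GH3.3) and -4.205 (AT3G21330). In asf1ab minus WT the values were 2.503 (AT5G50600), 1.887 (XTH15), 1.596 (AT5G14580), 1.533 (AT5G61590), 1.304 (BT5), 1.233 (ICME-LIKE2), -4.865 (AT5G51190), -2.299 (CAF1a), -2.232 (AT4G27280), -2.018 (AT2G22200), -1.912 (CBF2) and -1.867 (ERF5). In hira minus WT they were 2.072 (AT5G53895), 1.791 (AT4G34950), 1.762 (FIB), 1.660 (AT5G61590), 1.622 (AT1G72416), -4.749 (AT5G51190), -2.945 (AT4G27280), -2.883 (CAF1a), -2.822 (CBF2) and -2.628 (MYC2). The fitted values of AT4G07975 (4.275) and AT2G22880 (-3.747) rest on groups listed at 0 and are no measured folds.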

How the results depend on the processing

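Of the 816 called values of named genes, 230 lost their call when a library was left out, with another pseudocount or after rescaling, and 0 reversed; the other alternatives were not run for single genes. Of these values 37 lost the call with a pseudocount of 0.1, 37 with 5 and 42 after rescaling, all with the direction kept. Leaving out the white-light hira replicates 1 and 2 together, and leaving out ribosomal and organelle transcripts with rescaled totals, were chosen after seeing the data. The cause was not tested unless named.

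With a change of at least 1 log2 unit, a stricter threshold, counts were 919, 1073, 1118 and 1015 for shade in WT, pif7, asf1ab and hira. The differences in pif7, asf1ab and hira gave 399, 48 and 121, and white light gave 38, 896 and 416. With only the groups compared, which leaves fewer libraries to estimate the spread, the differences in asf1ab and hira gave 45 and 56 and white light gave 24, 2324 and 183 for pif7, asf1ab and hira. Rescaling by the median of ratios gave 1421 for hira in white light. Without white-light hira replicates 1 and 2 together, hira gave 66 for the difference and 292 in white light, where the lone library is assumed to vary like the other groups.

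Leaving out 1 library gave 3875 to 4813 genes for shade in WT, 6291 to 8489 in pif7, 4987 to 5431 in asf1ab and 5336 to 7092 in hira. Counts were 500 to 2630, 34 to 154 and 89 to 1773 for the differences in pif7, asf1ab and hira, and 33 to 104, 3146 to 4063 and 839 to 4248 in white light. For the pif7 difference (1167) the moved counts were 614 without WT_white replicate 1, and 596, 626 and 2630 without pif7_white replicates 1, 2 and 3, 741, 626 and 720 without WT_shade replicates 1, 2 and 3, and 500 and 740 without pif7_shade replicates 1 and 3. For asf1ab (88) they were 51 and 52 without WT_white replicates 1 and 2, 48, 46 and 144 without asf1ab_white replicates 1, 2 and 3, 38, 46 and 39 without WT_shade replicates 1, 2 and 3, and 39, 34 and 154 without asf1ab_shade replicates 1, 2 and 3. For hira (247) they were 139 and 125 without WT_white replicates 1 and 2, 124, 93 and 1773 without hira_white replicates 1, 2 and 3, 96, 158 and 122 without WT_shade replicates 1, 2 and 3, and 89, 106 and 119 without hira_shade replicates 1, 2 and 3. In white light pif7 (76) gave 33 without WT_white replicate 1 and 35 without pif7_white replicate 2. There hira (2228) gave 1420 and 1240 without WT_white replicates 1 and 2 and 839, 1253 and 4248 without hira_white replicates 1, 2 and 3.

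Of the 25 lists, the preset correlation called 6, 7 and 14 for shade in pif7, asf1ab and hira, 12, 10 and 10 for the differences and 4, 6 and 7 in white light. The estimated correlation called 0, 3 and 4, then 6, 2 and 2, and 0, 0 and 0. With fry 10 and 12 were called for shade in pif7 and asf1ab, 3 and 2 for the differences in asf1ab and hira, and 1, 10 and 4 in white light. With a pseudocount of 0.1 the asf1ab difference kept 6. The share of the WT response, for genes induced in WT, was 0.658, 0.932 and 0.933 in pif7, asf1ab and hira for genes changed by at least 1 log2 unit and 0.690, 0.981 and 0.818 after rescaling. With a pseudocount of 0.1 the excess covariance in white light was 0.0207 for pif7 and hira and 0.214 for asf1ab and hira.

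With the replicate number as a replicate block, shade counts were 5209, 8497, 6113 and 6969, differences 1230, 88 and 239, and white light 82, 4512 and 2655. Residuals of the same number correlated from -0.152 to 0.314, above 0.1 in 24 of 84 pairs, with a median of 0.0455 against -0.0305 for different numbers. Of 24 libraries 16 lay closest to their own number, a hint from the data, as the labels name no pairing. The 2-decimal FPKM and an estimated depth of 13400000 to 18200000 reads limit weakly expressed genes.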

Other observations

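The gene lists in this part, their members and the neighbour and replicate values were chosen after the values were seen, so their p-values are descriptive. Sulfur assimilation genes fell with shade in every genotype. In WT 11 of 12 fell, 11 adjusted over the list alone, the APS reductase genes APR1 by -2.065 ± 0.161 and APR2 by -1.94 ± 0.143 and the sulfur-starvation gene LSU2 by -2.38 ± 0.274 (median -1.46, adjusted p = 1.72e-09). In pif7 9 fell and SULTR2;1 rose, in asf1ab 9 fell and in hira 8 fell, at medians of -1.43 (rescaled -1.54), -1.14 and -1.04 (rescaled -1.17). For asf1ab the list had adjusted p = 0.114 with an estimated correlation. All 11 anthocyanin and flavonoid genes fell in shaded pif7, LDOX by -3.24 ± 0.391, the transport gene GSTF12 by -3.18 ± 0.375 and DFR by -2.91 ± 0.442 (median -2.51, adjusted p = 1.18e-12), where 4 fell in WT and 3 each in asf1ab and hira. For 7 of 11 the response in pif7 was lower than in WT (median -1.72, adjusted p = 4.96e-11, and adjusted p = 0.089 with an estimated correlation). In white light 4 of 11 were higher in pif7 than in WT, 11 adjusted over the list alone (median 1.26, adjusted p = 3.15e-22), and 5 were lower in asf1ab.

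In the list of endoplasmic reticulum chaperones 10 of 12 genes rose in shaded hira, with BIP2 at 1.96 ± 0.193 (median 1.28, rescaled 1.12, camera adjusted p = 9.68e-08, and adjusted p = 0.0728 with an estimated correlation). UTR3, a list member that is not a chaperone gene, rose by 2.13 ± 0.213. Of the 12 genes 6 rose more than in WT, BIP2 by 1.54 ± 0.272 (camera adjusted p = 7.53e-09, and adjusted p = 0.0747 with an estimated correlation). In WT 5 rose, or 8 adjusted over the list alone, and in pif7 and asf1ab 10 each. In neither pif7 nor asf1ab was the response of any of the 12 called different from WT (camera adjusted p = 0.13 and adjusted p = 0.0662). Stress-related ERF, zinc-finger and CBF factor genes all fell in shaded hira, 13 of 13, WRKY33 by -2.77 ± 0.410 and ERF6 by -2.40 ± 0.300 (median -2.11, adjusted p = 4.96e-15), and 8 were higher in white-light hira, ERF6 by 1.59 ± 0.300 (median 1.34, adjusted p = 2.65e-19). Their shade response was lower than in WT for 9 of 13 in hira, 12 adjusted over the list alone (median -2.36, adjusted p = 1.14e-30), for 3 in asf1ab (median -0.961, adjusted p = 2.08e-13) and for 2 in pif7 (median -0.733, adjusted p = 1.52e-05, and adjusted p = 0.222 with an estimated correlation).

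MSTRG.19097 read 2.16 ± 0.633 FPKM in white-light WT and 11.98 ± 3.94, 10.2 ± 0.280 and 8.34 ± 1.56 in pif7, asf1ab and hira. MRD1 read 45.1 ± 2.47 FPKM in shaded pif7, 42.1 ± 4.81 in shaded hira, 0.187 ± 0.242 in shaded WT and 0.883 ± 0.516 in shaded asf1ab. Residuals of the white-light libraries with replicate number 3 correlated at a median of 0.199, where all white-light libraries of the same number gave 0.0645.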
